A study of Mus musculus with 8 samples.

How the data were processed

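RNA was measured in the olfactory mucosa of mice at postnatal day 30, in 4 control samples and 4 samples with the TE1 and TE2 deletion. Per the labels, total RNA was isolated with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq Stranded Total RNA kit, which depletes ribosomal RNA and keeps strand. Because ribosomal depletion keeps unspliced and non-polyadenylated RNA, gene values can include reads from nuclear transcripts. Per the submitters' processing notes, STAR 2.6.0 and DESeq2 were used with the genome build GRCm38.p6. The read counter, its strand setting and handling of reads that map to several places, and the annotation release are not given in the sources used here.

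The deposited table has 54982 rows, each a gene symbol with an Ensembl identifier, and 1 column per sample. The authors' per-sample values are a signal of gene read counts divided by a size factor, as the values themselves show. In each column every value is a whole multiple of the smallest one: 100% of the non-zero values came out whole within a tolerance of 0.001. Whole reads were recovered this way, and their sums per library were taken as depth, 31655524 to 50748777 reads. The table also holds the authors' own comparison: per the file headers, a base mean, a log2 fold change with its standard error, a test statistic used here only as a score, a p-value and an adjusted p-value. The authors' deposited log2 fold change is positive where the control is higher, and it is smaller in size than the ratio of the group means for the Taar genes. Values of that comparison are printed only where the authors' deposited table is named.

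Columns were matched to samples by the group and replicate number in their names. The columns of the deletion group carry another abbreviation than the sample titles, and were matched by their number and by being the only columns not named for the control. Rows were matched to GENCODE release M21, which uses the same assembly, by Ensembl identifier without version: 54161 matched and 821 did not, and 0 rows named no gene. Coordinates are 1-based positions in GRCm38. The symbols are those of the table, and some are clone names, beside which the reference symbol is given.

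The design had assumed raw counts with an edgeR quasi-likelihood test, and named limma on log2(value + 1) for scaled values. Since the values are scaled, the main test was limma 3.58.1 in R 4.3.3 on log2(scaled reads + 1), a linear model of deletion minus control with trend and robust variance moderation. Genes were kept with the filterByExpr function of edgeR 4.0.16 by group with a minimum count of 10, which left 21974 genes. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The count test on recovered reads, edgeR's quasi-likelihood test with TMM factors, was added as an alternative and called 16 genes, all 16 shared with limma. DESeq2 1.42.0 was another alternative. The main test was tested on simulated data for the deletion minus control comparison, drawn from the real means and library sizes over 21689 genes. It recovered 30% of 50 genes changed 1.5-fold, 65.3% of 49 changed 2-fold, 91.7% of 48 changed 4-fold and 93.9% of 49 changed 16-fold, with 10 false calls. The simulation changed 200 genes, more than the 16 called in the real data. The Benjamini-Hochberg adjustment is stricter with fewer changed genes, so these shares can overstate recovery here.

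Gene lists were fixed before the data were examined: 26 lists of Taar genes, genes beside their cluster, olfactory cell types and zones, neighbouring tissues, cell states, and sex-linked check genes. Odorant receptors and their class I and class II members were defined by Olfr number. Lists with at least 3 tested genes, 28 with the receptor lists, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 28 lists. The list of Taar1 and Taar7c-ps had too few tested genes. Lists share some genes, and marker lists can include genes that other cells of the mucosa also express.

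The genes named in the text follow a rule also set at that time. It takes all genes of the Taar lists and the list of neighbours, and up to 8 largest rises and 8 largest falls among other genes with an adjusted p under 0.05 and no overlap between groups. It adds the 5 odorant receptors with the smallest p that pass in each direction, or the 3 smallest where none passes, and up to 4 members with the smallest p of each list with a camera or fry adjusted p under 0.05. Gm10800, RP23-468A19.2, Xist, Ddx3y, Uty and the genes of single libraries in the closing part were chosen after their values were seen.

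Summed CPM, detected receptors and shares of reads were compared by two-sided exact permutation tests over the 70 splits of 8 libraries, adjusted over 14 measures. Receptors were counted at 10 or more reads after thinning every library to 31655524 reads. Folds of Taar genes were also computed from pooled reads with exact 95% binomial counting intervals, with a floor of 3 reads over the group where the deletion libraries had 0. Background was measured on single-exon Tas2r, Krtap and Ifna genes; Vmn1r genes were dropped from that set before the test was run. Sequencing reads are not independent molecules, so these intervals and floors cover counting error only.

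Alternatives set before the data were examined were other scalings by library totals, looser and stricter filters, DESeq2, limma-voom with quality weights, limma without robust moderation, a replicate block, the mature neuron markers as a covariate, a test against a 1.5-fold change, other denominators and thresholds, and leaving out each library in turn. The median-of-ratios size factors listed among them are those of the deposited values, so TMM factors were run in their place. TMM factors, pseudocounts of 0.5 and 5, the edgeR test, and leaving out control replicate 3 and deletion replicate 4, alone or with control replicate 2 and deletion replicate 3, were added after seeing the data. Labels give no sequencing batch or date. Figures were drawn with matplotlib 3.10.9.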

Results

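RNA sequencing was used to ask how the expression of the olfactory trace amine-associated receptor (Taar) genes depends on 2 candidate enhancers, TE1 and TE2. Taar genes encode a small family of G protein-coupled receptors for volatile amines, and each olfactory sensory neuron that uses one expresses it in place of an odorant receptor. Total RNA was taken from the olfactory mucosa, the lining of the nasal cavity that holds the olfactory sensory neurons, of mice at postnatal day 30. There were 4 libraries from control mice and 4 from mice with the TE1 and TE2 deletion. The positions of the deleted segments are not given in the sources used here. The animals were labelled as male on a 129S6;C57BL/6J background. The samples of a group carry only a number in the labels, which do not say whether each is a separate animal. The values set the libraries apart, but do not show for each pair that the animals were separate. Between any 2 libraries of a group, 10 to 66 genes outside the Y chromosome and Xist differed at least 8-fold. These genes had 100 or more scaled reads in the higher library. Deletion replicates 1 and 2 were the closest pair, with 10 such genes. Deletion replicate 3 differed from the others in its sex-linked genes. The antisense gene RP23-468A19.2 (BC018473 in the reference annotation) had 12.8 scaled reads in control replicate 4 against 1735 to 2976 in the other controls.

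Reads assigned to genes numbered 50748777, 40409415, 31655524 and 40516222 in control replicates 1 to 4, and 37410384, 36359734, 44114750 and 43649337 in deletion replicates 1 to 4. Values are reads per gene divided by the library's size factor, called scaled reads here, and fold changes are on the log2(scaled reads + 1) scale, deletion minus control, which understates the change of genes with few reads. No pair of libraries of a group agreed within sampling noise, with chi-square values per gene from 9.85 to 268.

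The Taar genes lost nearly all of their expression in the deletion mice. The 14 olfactory Taar genes together took 82.4 ± 10.3 CPM (recovered reads scaled to the library total) in controls and 0.780 ± 0.757 in deletion libraries (SD, n = 4 each), a change of -99.1% (-99.5% without deletion replicate 4). This difference was far larger than the spread between replicates and reached the smallest p that 4 against 4 libraries can give, 0.0286 (exact permutation test, two-sided, 70 splits; 0.4 after Benjamini-Hochberg adjustment over 14 measures). Control replicates 1 to 4 held 3579, 3594, 2941 and 3133 Taar reads, and deletion replicates 1 to 4 held 13, 11, 25 and 83. Every deletion library therefore held far fewer Taar reads than any control, and deletion replicate 4 held the most residual reads. The genotype labels were not checked apart from these reads, which are the outcome itself.

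All 12 olfactory Taar genes with enough reads to test fell (limma, Benjamini-Hochberg adjusted p from 2.9e-06 to 0.0061), and 12 of 12 also passed when adjusted over the list alone. Their log2 fold changes ran from -7.92 to -4.58 with a median of -5.94. With the 2 untested genes set at their bounds, the median over all 14 was -5.85. The genes lie on chromosome 10 in GRCm38, and the family, from Taar1 to Taar9, spans positions 23920356 to 24109534. All but Taar2 are annotated with a single exon.

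The most abundant members in controls were Taar7b, Taar6 and Taar7d. Taar6 (ENSMUSG00000045111.5, 23984609 to 23985646, minus strand) fell from 2193 reads over the 4 controls to 9 over the deletion libraries, a log2 fold change of -7.92 ± 0.56 (SE). Taar7d (ENSMUSG00000095569.1, 24027222 to 24028298, plus strand) fell from 542 ± 90.7 to 3.65 ± 1.94 and had the smallest adjusted p, 2.9e-06 (limma). Taar7b changed from 545 ± 73.7 to 3.82 ± 3.83 scaled reads. Taar9 (24108488 to 24109534, minus strand), at the far end of the cluster, fell from 475 ± 75.0 to 1.84 ± 3.07 scaled reads, or 238-fold by pooled reads (95% counting interval 121 to 553). Of its 8 deletion reads, 7 were in deletion replicate 4, and without that library the fold rested on 1 read (1382-fold, interval 248 to 54622). Taar4 changed from 245 ± 39.1 to 3.35 ± 3.01 scaled reads.

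Taar2 (ENSMUSG00000059763.4, 23938572 to 23941583, plus strand) kept 2.56% of its control level, with 1289 reads in all controls and 32 in all deletion libraries. Taar3 kept 4.07%, the highest share among the tested genes when all libraries are used, and was 24.5-fold lower (95% counting interval 12.7 to 54.4), but 7 of its 9 deletion reads were in deletion replicate 4. Without that library Taar3 kept 1.25% (80.1-fold lower, interval 21.9 to 665) and Taar2 kept 1.44%, the highest share. Taar3 lost its call when control replicate 1 (adjusted p = 0.0597) or control replicate 3 (adjusted p = 0.0568) was left out of the limma test. Taar5 fell 79.8-fold (interval 27.0 to 389), from 247 reads to 3, all 3 in deletion replicate 4, so without it no read was left. Leaving out deletion replicate 4 moved the pooled-read fold by over 1.5 times for 11 of the 12 tested genes, all but Taar7d, each toward a larger loss, and leaving out any other library did so for 0. Of the Taar7 subfamily, Taar7a changed from 181 ± 43.8 to 2.39 ± 2.28 scaled reads, Taar7e from 130 ± 22.3 to 1.66 ± 1.54 and Taar7f from 125 ± 31.9 to 1.84 ± 2.58. These Taar7 genes and the 3 Taar8 genes are near-identical paralogs, so the split of reads among them is uncertain.

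Taar8c fell from 119 reads to 1. Taar8a and Taar8b had too few reads to test, with 38 and 21 reads over the 4 controls and 0 in the deletion libraries. Against a floor of 3 reads over the group, Taar8a was at least 12.3-fold and Taar8b at least 6.78-fold lower. The 95% counting intervals, which also take in the counting error of the controls, reach down to 9.50-fold and 5.04-fold. Intervals and floors cover counting error only. Taar1, which is in the cluster but is not an olfactory receptor, had 3 reads in controls and 0 in deletion libraries, too few for a fold. The pseudogene Taar7c-ps had 13 and 1, a ratio of 12.6 (interval 1.89 to 535).

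**Figure D1:**
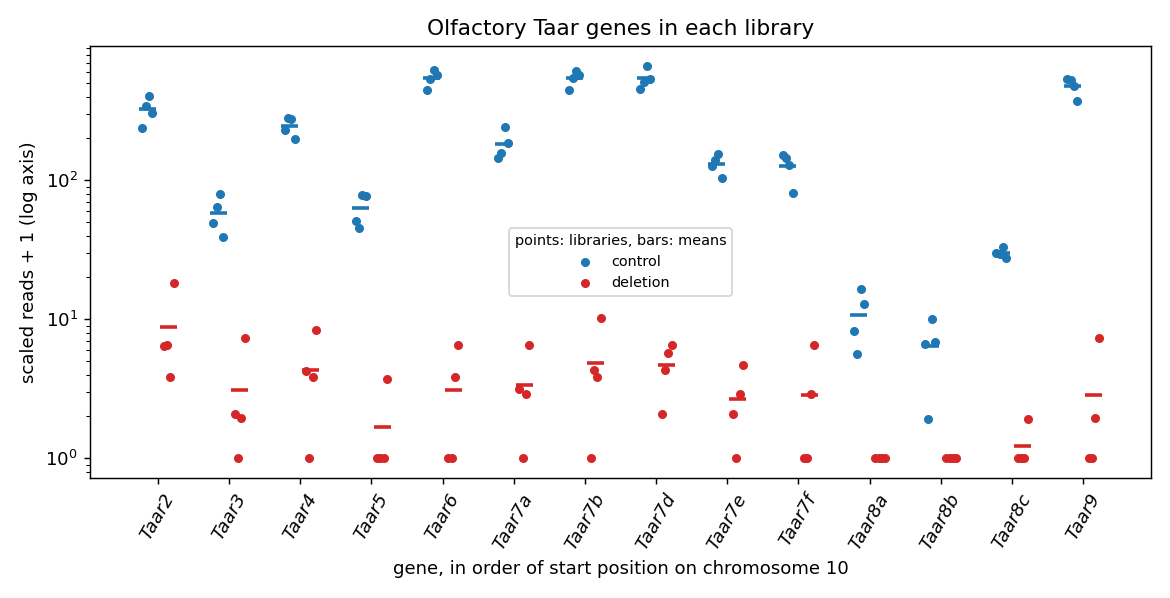
Scaled reads + 1 (log axis) of the 14 olfactory Taar genes, in order of position on chromosome 10, in each of the 4 control (blue) and 4 deletion (red) libraries, with bars for group means. The deletion points lie below the control points for each gene, and deletion replicate 4, with 83 Taar reads, holds the highest deletion point of most genes.

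The genes next to the cluster did not share this loss. None of the 10 fixed non-receptor neighbours passed (0 calls by limma, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05; 0 by edgeR and by DESeq2). Their log2 fold changes were 0.06 ± 0.07 (SE) for Eya4, 0.14 ± 0.09 for Rps12, which encodes a ribosomal protein, and 0.13 ± 0.11 for Slc18b1. They were 0.12 ± 0.08 for Stx7, 0.40 ± 0.40 for Ctgf, 0.15 ± 0.08 for Enpp1 and 0.22 ± 0.27 for Enpp3. Vnn1 was at 0.02 ± 0.25, Moxd1 at 0.01 ± 0.12 and Vnn3 at 0.00 ± 0.41, and these 3 signs turned negative when library totals were used as the scaling. Without deletion replicate 3, Enpp3 was at -0.0727. Leaving out 1 library at a time, Ctgf ran from 0.15 (without control replicate 1) to 0.72 (control replicate 4), and Stx7 from 0.0557 (control replicate 2) to 0.18 (control replicate 1). Rps12 ran from 0.0661 (control replicate 2) to 0.20 (control replicate 1), Slc18b1 from 0.0729 (deletion replicate 1) to 0.20 (control replicate 2), Eya4 from 0.0371 (control replicate 1) to 0.11 (control replicate 2) and Enpp1 from 0.12 (deletion replicate 2) to 0.22 (deletion replicate 4). Stx7 (24149302 to 24190222), the neighbour just past Taar9, was at 4799 ± 529 scaled reads in controls and 5188 ± 84.7 in deletion libraries (SD, n = 4). Among the 14 tested genes other than olfactory Taar genes within 1 Mb of the cluster, 0 were called and 0 had an unadjusted p under 0.05.

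Across the transcriptome few genes were called. In simulation with 200 changed genes the test recovered 30% of 1.5-fold and 65.3% of 2-fold changes, so smaller changes can be missed. With fewer changed genes the adjustment is stricter, so these shares can overstate recovery here. Of 21974 tested genes, 16 differed between deletion and control at an adjusted p under 0.05 (limma), 13 lower and 3 higher, and 12 of the 13 lower genes were olfactory Taar genes. A further 754 genes had an unadjusted p under 0.05, and the next smallest adjusted p was 0.869. The authors' deposited table lists 20 genes at an adjusted p under 0.05, 13 lower and 7 higher, and all 16 calls made here are among them. The deposited calls not made here were Rps15a-ps7, the class I receptors Olfr543 and Olfr568, and Hddc3, each higher in deletion (limma adjusted p = 0.869 each). The count of genes called here rose to 26 with DESeq2 and to 31 without deletion replicate 4, and was 10 when genes had to average 50 reads. Among higher genes alone it was 13 without deletion replicate 4, and 1 without deletion replicate 1, 2 or 3 or without control replicate 1, 2 or 3.

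The remaining lower gene was RP23-58L22.2 (ENSMUSG00000097327.7, E030030I06Rik in the reference annotation, a predicted protein-coding gene on chromosome 10 from 22113050 to 22149270, minus strand). It fell from 95.8 ± 26.4 to 3.67 ± 2.25 scaled reads (SD, n = 4), a log2 fold change of -4.47 ± 0.41 (SE; limma adjusted p = 0.00052), and ended 1.77 Mb before the start of Taar1. It was lower in 4 of 4 deletion libraries and kept its call in all 21 alternative settings that tested it against no change, and against a 1.5-fold change (adjusted p = 0.0011).

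Of the 3 higher genes, the odorant receptor Olfr298 (ENSMUSG00000062878.3, chromosome 7, 86486322 to 86492484, minus strand) rose from 233 ± 30.2 to 483 ± 50.8 scaled reads, a log2 fold change of 1.05 ± 0.13 (SE; limma adjusted p = 0.0053). Ect2l (ENSMUSG00000071392.6, chromosome 10, 18128903 to 18210890, minus strand) rose from 392 ± 41.5 to 667 ± 72.3, 0.76 ± 0.11 on the log2 scale (adjusted p = 0.0400), and lies 5.71 Mb before the cluster. RP23-430H1.2 (ENSMUSG00000026831.16, 1700007K13Rik in the reference annotation, chromosome 2, 28462001 to 28466332, minus strand) rose from 523 ± 43.8 to 791 ± 44.2, 0.60 ± 0.09 on the log2 scale (adjusted p = 0.0483). The groups did not overlap for any of these genes, but only Olfr298 kept its call in each of 22 alternative settings that test against no change. Against a 1.5-fold change none of the 3 was called (limma adjusted p = 1 each). RP23-430H1.2 lost it when any single library was left out (adjusted p from 0.0530 to 0.376), and Ect2l lost it when control replicate 1, 2 or 3 or deletion replicate 1, 2 or 3 was left out (highest adjusted p = 0.299). Other groupings of the 8 libraries gave up to 6 called genes outside the Taar family, with a median of 0. Of the 35 splits, 3 gave 4 or more, the real one included, so chance cannot be excluded for that count. Over all tested genes, 2.20% had groups that did not overlap, against 2.86% by chance for 4 against 4.

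**Figure D2:**
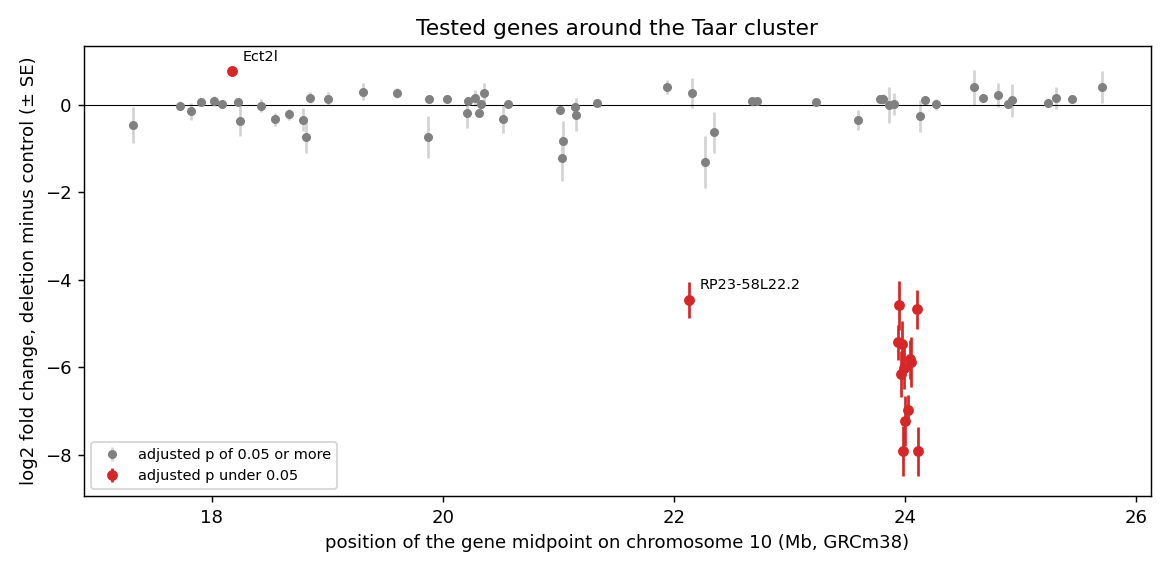
Log2 fold change (deletion minus control, bars ± SE) of the 72 tested genes between 17 and 26 Mb of chromosome 10 (GRCm38), against the position of the gene midpoint in Mb. The 14 called genes are red: 12 Taar genes from -7.92 to -4.58, RP23-58L22.2 at -4.47 and Ect2l at 0.76.

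The odorant receptors, the large receptor family used by most olfactory neurons, were nearly level between the groups. They took 6973 ± 672 CPM in controls and 7092 ± 340 in deletion libraries (SD, n = 4), a change of 1.71% that was within the spread between replicates (exact permutation p = 0.8, two-sided; 0.933 adjusted over 14 measures). The direction was not stable: the change was -1.54% without control replicate 2, -0.0722% without control replicate 4, -0.0668% without deletion replicate 4 and -1.63% over mature neuron reads, and it was 5.90% without control replicate 3, 3.88% without deletion replicate 3 and 2.88% without control replicate 1. After every library was thinned to the smallest total, 1028 ± 13.4 receptors had at least 10 reads in controls and 1028 ± 6.55 in deletion libraries (exact permutation p = 1). Taar genes and odorant receptors together took 7055 ± 674 and 7093 ± 341 CPM. The Taar sum alone changed by -81.6 CPM, small beside the control SD of 672 CPM of the receptor sum. These sums therefore cannot show whether Taar neurons turned to odorant receptors or were lost.

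Of 1039 tested odorant receptors, only Olfr298 was called, also when adjusted over the list alone, where the next smallest adjusted p was 0.549. At an unadjusted p under 0.05 (limma) there were 59, 42 higher and 17 lower, and none of 80 tested receptor pseudogenes was called. Without deletion replicate 4 the count of called receptors was 7, and DESeq2 called 3. Against a change of 1.5-fold, 0 receptors were called. No lower receptor passed, and the 3 with the smallest p were Olfr618 (274 ± 31.3 against 150 ± 61.8 scaled reads), Olfr560 (76.6 ± 22.4 against 29.6 ± 20.8) and Olfr592 (875 ± 214 against 576 ± 64.8; control first, adjusted p = 0.869 each). All 3 belong to the class I cluster on chromosome 7. Reads can be shared between similar receptors, so single receptors carry that uncertainty.

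Class I receptors, the evolutionarily older class, and class II receptors did not separate in their median change. The median log2 fold change was -0.03 over 116 class I and 0.09 over 923 class II genes, and the difference of -0.12 was within what other groupings of the libraries give (exact permutation p = 0.543). These medians depended on single libraries: with 1 left out, the class I median ran from -0.17 (without deletion replicate 3; -0.13 without control replicate 4) to 0.0216 (without control replicate 2). The class II median ran from 0.00899 (without control replicate 2) to 0.16 (without control replicate 3). No class I receptor was called by limma or by edgeR, DESeq2 called 2, and 3 were called by limma without deletion replicate 4. At an unadjusted limma p under 0.05 there were 15 of 116 class I receptors. The same held for 44 of 923 class II receptors and 770 of 21974 tested genes. This larger class I share was not tested, and a median cannot show changes in mixed directions. Camera gave an adjusted p of 0.0108 for class II, 0.0560 for class I and 0.0451 for all receptors. With an estimated correlation the adjusted p = 0.866 for each of these 3 lists, and the fry adjusted p was 0.890 for class II and for all receptors and 0.980 for class I.

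**Figure D3:**
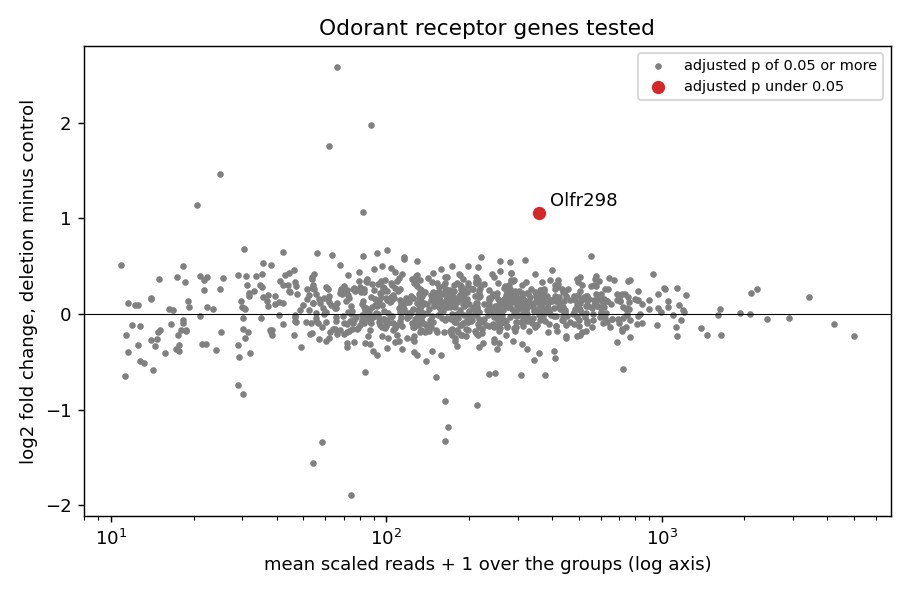
Log2 fold change (deletion minus control) of the 1039 tested odorant receptor genes against their mean scaled reads + 1 (log axis), one point per gene. Olfr298, at 1.05, is the only red point, which marks an adjusted p under 0.05.

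The cell types of the mucosa showed no called gene outside the receptor families. Of 28 lists tested with camera at a preset correlation, 8 had an adjusted p under 0.05, but with an estimated correlation only the Taar list passed (adjusted p = 0.0217), and only the Taar list passed fry (adjusted p = 0.00027). Without control replicate 2, 5 lists passed camera at the preset correlation. Respiratory epithelium markers had a median log2 fold change of 0.26 over 9 genes (camera adjusted p = 0.0040; adjusted p = 0.628 with an estimated correlation). Among them, Reg3g, a secreted antimicrobial lectin, was at 20992 ± 7472 scaled reads in controls and 31126 ± 3186 in deletion libraries, Bpifa1 at 216658 ± 55659 and 283544 ± 11261, and Tff2 and Krt18 at log2 fold changes of 0.56 and 0.22. Control replicate 2 was the lowest library for Reg3g (10853) and Bpifa1 (140059), and without it the log2 fold changes of Reg3g, Bpifa1, Tff2 and Krt18 were 0.36, 0.23, 0.27 and 0.13.

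Sustentacular cell markers, which include xenobiotic-metabolising cytochrome P450 enzymes, had a median of 0.17 over 13 genes (camera adjusted p = 0.0145; adjusted p = 0.628 with an estimated correlation). Cyp2a5 was at 0.24 ± 0.11 (SE), Cyp1a2 at 0.22 ± 0.10, Ermn at 0.24 ± 0.11 and Cyp2g1 at 0.19 ± 0.11 on the log2 scale, none of them passing. Horizontal basal cell markers had a median of 0.27 over 7 genes (camera adjusted p = 0.0343; adjusted p = 0.801 with an estimated correlation), with the keratins Krt15 at 1.02 ± 0.60, Krt14 at 0.28 ± 0.21 and Krt5 at 0.27 ± 0.17, and the basal transcription factor Trp63 at 0.18 ± 0.12. Immediate early and stress genes had a median of 0.22 over 13 genes (camera adjusted p = 0.0059; adjusted p = 0.318 with an estimated correlation), with Nr4a1 at 0.44 ± 0.21, Atf3 at 0.37 ± 0.19, Junb at 0.34 ± 0.15 and the chaperone gene Dnajb1 at 0.20 ± 0.12. Control replicate 2 weighed on several of these values: without it Cyp2g1 was at 0.0706, Ermn at 0.14, Krt15 at 0.64, Krt14 at 0.0691, Krt5 at 0.16, Junb at 0.22 and Dnajb1 at 0.0867. Without control replicate 4, Krt15, Krt14 and Krt5 were at 1.53, 0.46 and 0.45. Without deletion replicate 1, Nr4a1 and Atf3 were at 0.23 and 0.20, without deletion replicate 3 Cyp2a5 was at 0.15, and without control replicate 1 Trp63 was at 0.0953. With other single libraries left out, Trp63 reached 0.29 and Dnajb1 0.32.

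Markers of olfactory bulb tissue, which a dissection can carry over, had a median of -0.36 over 9 genes (camera adjusted p = 0.0451; adjusted p = 0.628 with an estimated correlation). Gad1, an enzyme of GABA synthesis, was at 41.8 ± 35.6 scaled reads in controls and 8.11 ± 6.64 in deletion libraries, with control replicate 2 at 92.4. Gfap was at a log2 fold change of -0.83 ± 0.33 (SE), Tbr1 at 54.0 ± 19.2 and 32.8 ± 6.30 scaled reads (SD), and the oligodendrocyte gene Mobp at 24.0 ± 20.2 and 9.45 ± 5.24. None of these passed (limma adjusted p = 0.869 each). Control replicate 2 also had the lowest median correlation with the other libraries, 0.976. Mobp was at 54.1 scaled reads in control replicate 3 against 10.8 to 16.6 in the other controls. Leaving out 1 library at a time, its log2 fold change ran from -1.39 to -0.65. The 3 list members that went the other way were Eomes at 0.27, Slc1a2 at 0.0954 and Aqp4, the most abundant member, at 0.17.

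Lists of neurons and their states had no called member and camera adjusted p-values of 0.266 or more. The median log2 fold change was 0.07 for mature olfactory neurons, 0.06 for immature olfactory neurons, -0.02 for neuronal progenitors and dividing cells, 0.02 for receptor choice and receptor transport factors, 0.07 for guanylyl cyclase D neurons, -0.02 for activity-dependent genes, 0.12 for the dorsal zone and -0.06 for the ventral zone. The mature neuron list took 15616 ± 982 CPM in controls and 16155 ± 679 in deletion libraries (exact permutation p = 0.457). Among other cell types and states, the median was 0.04 for Bowman gland and nasal gland cells, 0.08 for microvillar and brush cells, 0.09 for olfactory ensheathing glia, -0.04 for the vomeronasal organ, -0.16 for blood and vessels, 0.02 for immune cells, -0.02 for bone, cartilage and muscle, -0.02 for interferon response genes and 0.09 for circadian clock genes, with camera adjusted p-values from 0.236 to 0.972. The genes beside the Taar cluster, tested as a list, had a camera adjusted p of 0.0560 and a fry adjusted p of 0.686. The medians of the immune and vomeronasal lists differ in sign from their camera direction.

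Library-level measures did not differ beyond the spread between replicates. Mitochondrial genes took 2.21 ± 0.261% of reads in controls and 2.37 ± 0.267% in deletion libraries (exact permutation p = 0.514), ribosomal protein genes 1.48 ± 0.163% and 1.58 ± 0.036% (p = 0.343), and histone genes 0.259 ± 0.030% and 0.274 ± 0.046% (p = 0.657). The 10 most abundant genes took 8.68 ± 3.61% and 7.22 ± 1.13% (exact permutation p = 0.629). Among these genes, the predicted gene Gm10800 took 7.87% of reads in control replicate 3, 2.27% in deletion replicate 4, 1.41% in control replicate 4, 0.752% in control replicate 2 and at most 0.046% in the other libraries.

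The sex-linked genes did not match the label of 1 library. Deletion replicate 3, labelled male, held 15300.3 scaled reads of Xist, the X inactivation transcript, against 4.86 to 86.9 in the other 7 libraries. It held 5.69 scaled reads of the Y-linked gene Ddx3y, against 2716 to 3087 in the others, and 17.1 of Uty, against 2594 to 2994. The 5 sex-linked genes had a median log2 fold change of -2.02 between the groups, set by this library (camera adjusted p = 0.0745; 0 called). Without deletion replicate 3, 14 genes were called, all 14 among the 16, including all 12 Taar genes.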

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

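The tests of silent genes, transcription and other groupings below were set before their results were seen, and the tests of called genes other than Taar genes, carry-over, haplotype windows, scaling and chromosome 7 were chosen only afterwards. The rules for reading the transcription, carry-over, window, scaling and chromosome 7 tests were also changed after their results were seen. Over 141 groups of 4 libraries, 23 had 1 library far from the other 3 relative to the group's range (gap ratio above 0.829), where chance gives about 1 in 20, or 7.05. In 3 of these the other 3 libraries had 0 reads, which fixes the ratio at its maximum. Without such groups, 20 of 138 remain, against 6.9 by chance. The chance rate holds for independent, normally distributed values. The groups here share items, such as single Taar genes and their sum, many reads are few, and Gm10800 was chosen after its values were seen. The excess over chance therefore cannot be read as a result.

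The counts of calls were set against other groupings of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 split) gave 16 called genes, with 6 as the highest other. Only the real one (1 split) gave 12 called Taar genes, with 0 as the highest other. Such a result, 1 of 35, is the smallest share this test can give. Every other split mixes libraries with many and with few Taar reads in a group, which widens the spread. Its lack of Taar calls thus follows from the loss itself, and 12 of the 16 calls are Taar genes. Without the Taar genes the real split gave 4 called genes, and 3 of 35 splits gave as many (highest other 6), so chance cannot be excluded for that count. For called odorant receptors, 2 of 35 splits gave as many as the real split (1 gene; highest other 2), and for lists passing camera 14 of 35 did (8 lists; highest other 12), so chance cannot be excluded. The neighbours of the cluster and the class I receptors had 0 calls, which all 35 splits gave or exceeded (highest other 0 for both).

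The reads left on Taar genes were concentrated in deletion replicate 4, which had 1.90 CPM of Taar reads against 0.303 to 0.567 in the other deletion libraries. It stood apart for Taar9 (6.39 scaled reads, from 7 reads) and Taar3 (6.39, from 7), and held the only reads of Taar5 (2.74, from 3), Taar8c (0.913, from 1) and Taar7c-ps (0.913, from 1) in the deletion group, where the counts are too low to set it apart. Carry-over from control libraries would spread these reads in proportion to control levels and stays open: chi-square was 72.2 over 14 genes (p = 7e-05 by simulation, with reads treated as independent molecules, which they are not) but 29.4 (p = 0.025) without deletion replicate 4. Background such as genomic DNA, measured on 99 single-exon Tas2r, Krtap and Ifna genes, stays open: Taar reads per kb lay above the range of 10000 random gene draws in 1 of 4 deletion libraries, replicate 4, at 5.65 against an upper limit of 3.35. Low transcription of Taar genes in some neurons also stays open with the same count of 1 library; the limit set beforehand to exclude it was too loose, since draws of silent genes in deletion replicate 1 reached 2.34 reads per kb, above its 0.885 for Taar genes.

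The called genes outside the Taar family may reflect haplotypes of the mixed 129S6;C57BL/6J background. Scaling is argued against, since under TMM factors and library totals the log2 fold changes nearest 0 were 1.02 for Olfr298, -4.47 for RP23-58L22.2, 0.74 for Ect2l and 0.57 for RP23-430H1.2. The first 3 kept their calls, while RP23-430H1.2, close to the threshold, lost it under library totals as 0.60 ± 0.09 went to 0.57 ± 0.10 (SE; limma adjusted p = 0.152). Around Olfr298, 17 of 194 other tested genes within 10 Mb had a limma p under 0.05. This share was at percentile 97.8 of 495 windows of 20 Mb, above the limit set for a haplotype difference on chromosome 7. The windows overlap and were not matched for odorant receptors. Of these receptors 59 of 1039 had such a p, against 770 of 21974 tested genes, so the test cannot decide. The shares of 7 of 352 around RP23-430H1.2, at percentile 23.2, and of 6 of 105 around the Taar cluster, at percentile 87.5, are ordinary among windows and leave open haplotypes at RP23-430H1.2, RP23-58L22.2 and Ect2l, as well as an untested effect of the deletion.

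Deletion replicate 4 also departed from the other deletion libraries at genes of chromosome 7, such as Hddc3 (264 scaled reads against 554 to 592; controls 227 to 302) and Olfr304 (7.31 against 40.7 to 53.1; controls 8.85 to 11.6). At Olfr298, also on chromosome 7, this library stayed above the controls (432 scaled reads against 200 to 271). Segregating haplotypes are a candidate explanation of the departures. Of 24 genes at which this library stood apart, 5 lay on chromosome 7, against 2.48 expected with receptors drawn from receptors (permutation p = 0.093, unadjusted; 0.742 over the 8 libraries), too few genes to decide. No genotype was analysed here, and no other biological explanation was tested.

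Other libraries stood apart in values given here without explanation. Deletion replicate 3 had 15300.3 scaled reads of Xist, 5.69 of Ddx3y and 17.1 of Uty, against its male label, and 408042 of Cyp2a5, 18.0 of Vnn3 and 862 CPM of class I receptors, all of these last 3 above the rest of its group. Deletion replicate 1 had 279 scaled reads of Atf3, 18517 of Krt18 and 1018 detected receptors. Deletion replicate 4 had 902935 scaled reads of Gm10800, 8.92% of reads in the 10 most abundant genes and 39069 genes with a read after thinning. That gene count was also high in control replicates 2 to 4, at 37192, 45146 and 35980. It was 30870 in control replicate 1 and 30635 to 31632 in the other deletion libraries. Control replicate 3 had 54.1 scaled reads of Mobp, 10.3 of Taar7c-ps, 1048 detected receptors and 1108 receptors with a read before thinning. Control replicate 1 had 56.7 scaled reads of RP23-58L22.2, against 106 to 115 in the other controls.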

How the results depend on the processing

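The alternatives with TMM factors, other pseudocounts, edgeR and left-out groups of libraries were chosen after seeing the data. All 16 called genes kept their direction in each setting that tested them. In the settings that test against no change, 13 of these kept their call throughout, Taar3 lost it in 2 of 21 settings, Ect2l in 12 of 22 and RP23-430H1.2 in 16 of 22. Against a 1.5-fold change 13 of the 16 were called, the 12 Taar genes and RP23-58L22.2, and Olfr298, Ect2l and RP23-430H1.2 were not. The count of called genes was 10 with a mean of at least 50 reads, where fewer Taar genes were tested, 26 with DESeq2, 27 without control replicate 3 and deletion replicate 4, and 53 without control replicates 2 and 3 and deletion replicates 3 and 4, of which 14 were shared with the 16. The last left 39 lower and 14 higher genes; the higher count was 1 with the stricter filter, without robust moderation or with the neuron covariate, 10 with DESeq2 and 12 without control replicate 3 and deletion replicate 4. Called odorant receptors numbered 3 with DESeq2, 7 and 11 in these left-out groups of libraries, and 0 against a 1.5-fold change; class I calls numbered 2, 4 and 5. Lists passing camera numbered 15 without the filter, 5 with the stricter filter and 3 with limma-voom. The causes were not tested.

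Leaving out single libraries gave 13 to 31 called genes, 1 to 13 of them higher, 1 to 7 called receptors, 0 to 3 class I and 5 to 10 lists; the highest of each gene count came without deletion replicate 4 (31, 13, 7 and 3), and the 5 lists came without control replicate 2. The change in receptor sum ran from -1.54% to 5.90%, in detected receptors from -0.32% to 0.63% and in histone share from -1.28% to 13.2%. Enpp3 ran from -0.0727 to 0.36, Moxd1 from -0.10 to 0.11, Vnn3 from -0.27 to 0.27 and Vnn1 from -0.13 to 0.13. The receptor sum changed by -1.63% over mature neuron reads, and detected receptors by 0.81% at 50 reads.

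Signs turned in 32 gene values, none of a called gene. With library totals Moxd1 was at -0.0162, Vnn3 at -0.0231 and Vnn1 at -0.00437; with DESeq2 Moxd1 at -0.00329 and Vnn3 at -0.0558; with limma-voom Enpp3 at -0.0341, Ctgf at -0.0145, Moxd1 at -0.0204, Vnn3 at -0.34 and Vnn1 at -0.14; with the neuron covariate Moxd1 at -0.10 and Vnn3 at -0.14; with edgeR Moxd1 at -0.0190 and Vnn3 at -0.0647; and with a pseudocount of 5 Vnn3 at -0.0132. Without control replicates 2 and 3 and deletion replicates 3 and 4, Enpp3 was at -0.29, Moxd1 at -0.0690, Vnn3 at -0.20, Vnn1 at -0.20, Tff2 at -0.00498, Krt14 at -0.0928, Krt5 at -0.0737 and Rps12 at -0.0136, and the receptor Olfr618 was called (limma adjusted p = 0.0311).

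The labels do not say whether the replicate numbers pair the samples. Same-number correlations were 0.36, 0.03, -0.34 and 0.16, within the range of the different-number ones, -0.35 to 0.47. These values give no sign of pairing but cannot exclude it. With a replicate block 14 genes were called, 1 of them higher, with 12 Taar genes and 8 lists. In the replicate block the change in Taar sum stayed at -99.1%, but 4 pairs cannot give an exact sign-flip p below 0.125. Depth limits Taar8a and Taar8b, with 38 and 21 control reads. Of changes of 1.5-fold, 30% were recovered in simulation at the depth and number of libraries used here. That simulation had 200 changed genes, which can overstate recovery in these data.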

Other observations

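At some genes a single library differed several-fold or more from the other replicates of its group. These genes were chosen after their values were seen. The olfactory receptor gene Olfr320 on chromosome 11 (58681099 to 58686233) had 11.9, 16.5 and 15.2 scaled reads in deletion replicates 1 to 3 and 136 in deletion replicate 4, with 61.9 to 126 in controls. The receptor pseudogene Olfr587-ps1 on chromosome 7 had 103, 80.4 and 90.0 in deletion replicates 1 to 3 and 8.22 in deletion replicate 4, with 8.10 to 15.7 in controls. Tmem221 on chromosome 8 had 12.8 scaled reads in control replicate 4 and 18.3 in deletion replicate 4, against 164 to 392 in the other 6 libraries.

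Control replicate 2 stood apart from the other controls at 146 of 19396 genes, the most of any library, followed by deletion replicate 3 with 53 and deletion replicate 4 with 24. Of the 146 genes of control replicate 2, 32 are protein-coding, 65 belong to the annotation's provisional class TEC, and 10 are sense intronic, 10 antisense and 12 lincRNA genes. The nuclear RNA Malat1 took 0.651% of its reads, against 0.296% to 0.417% in the other libraries. Silent-gene reads, over the Tas2r, Krtap and Ifna genes, were at 3.10 per kb in control replicate 3, 1.48 in deletion replicate 4, 1.08 in control replicate 2 and 0.344 to 0.848 in the other libraries.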
